A study of Homo sapiens with 6 samples.

How the data were processed

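RNA was measured by sequencing in H2122 cells, a human lung adenocarcinoma line, 48 hours after transfection with a control shRNA or with an shRNA against LYCAT, an older name of the gene LCLAT1. There were 6 libraries, 3 for each shRNA. The labels name total RNA as the molecule and do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

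The authors deposited 1 table of counts per gene for all 6 libraries, with gene symbols as identifiers. Per the submitters' processing notes, bcl2fastq 2.17, BWA 0.7.15, Bowtie2 and featureCounts 1.5.1 were named, with the genome builds hg19 and mm10. Which aligner and which build made this table, and whether counting used strand, is not given in the sources used here. The values were whole numbers with library totals that differ, as raw counts have, and the symbols are human. The columns of the LYCAT shRNA group carry a name that reads as a misspelling of LYCAT; they were assigned to that group by this name, and the replicate number came from the same name. No coordinates are printed, because the reference annotation used here (GRCh38, GENCODE v29) is not a build that the notes name.

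The table held 23368 genes, of which 7185 had a count of 0 in every library. Library totals were 4622452, 4930079 and 4075367 counts for control shRNA and 4730453, 3118946 and 4319597 for LYCAT shRNA. A level of 3 counts corresponds to 0.609 to 0.962 CPM (counts scaled to library size, per 1000000) in these libraries, so genes near that level were measured with little precision. The 10 most abundant genes took 4.49% to 4.87% of the counts of a library.

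Low counts were removed with filterByExpr by group in edgeR 4.0.16 (R 4.3.3), which left 11097 genes holding 99.77% of the counts. Libraries were scaled with TMM factors (0.993 to 1.01), and CPM values use the scaled library sizes unless stated. The comparison of LYCAT shRNA with control shRNA used edgeR's quasi-likelihood F test (estimateDisp, glmQLFit with robust=TRUE, glmQLFTest) with group as the only term. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are described as changed. The standard error (SE) of a log2 fold change was computed as its size divided by the square root of the F statistic. Means are given with the SD over the 3 libraries of a group. LCLAT1 was also tested with an exact two-sided permutation test on log2 CPM, for which 3 against 3 libraries cannot give a p below 0.1.

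Lists of genes were fixed before the data were examined: 25 lists of pathways, cell type markers and RNA quality signs, of which 24 had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. The same test with the correlation estimated from the data, fry, and camera on ranks were alternatives. The list of mitochondrially encoded genes had 0 of its 13 members in the table and was not analysed here.

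The rule for the genes named was also fixed before the data were examined. It takes LCLAT1, the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among changed genes with a mean of at least 5 CPM and no overlap between the groups. Unnamed loci, small RNAs of fixed classes, ribosomal pseudogenes and antisense transcripts were left out of these. From each list it takes the changed member with the smallest adjusted p in each direction and up to 2 more, or up to 2 abundant members where none changed. Some other genes are named, and the text says that they were chosen after their values were seen. Single members of the lung lineage list are not reported here.

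The edgeR fit, DESeq2 and limma-voom were tested on simulated counts for the same 11097 genes with 200 changed genes. With edgeR the simulated comparison of the 2 groups recovered 62% of genes changed 1.5-fold and 82% of genes changed 2-fold, and 2.04% of its calls were false. DESeq2 recovered 52% and 79% with 0.758% false calls, and limma-voom 61% and 82% with 6.54% false calls, above the 5% aimed for. In a separate simulation that shifted only 1 list by 1.3-fold, camera called that list and 0 of the unshifted lists. Genes were simulated independently of each other there, so it could not test for false calls that come from correlation between genes.

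Alternatives planned before the data were examined were DESeq2's size factors, library totals without scaling, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a replicate block, glmTreat against a 1.5-fold change, robust=FALSE, and leaving out each library. Added after seeing the data were offsets corrected by loess for GC content and transcript length, counts thinned to the shallowest library, and a fit without control shRNA libraries 1 and 2. GC content, length and chromosome came from the reference annotation by symbol, older symbols included. Of the tested genes, 10832 (97.6%) had a GC content and length, and 10808 had a chromosome shared with most of the 10 genes listed on either side.

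For runs of neighbouring genes, medians of log2 fold changes were taken in windows of 40 tested genes along each chromosome in the order of the table, and compared with 1000 shuffles of the gene order. This scan was tested on shuffled data with a lowered window. X-linked genes were compared with 100000 permutations and 10000 bootstrap samples. Lists for these tests, and 8 further pathway lists, were written after the data were seen. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.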

Results

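Expression was compared in H2122 cells, a human lung adenocarcinoma line, between 3 libraries with a control shRNA and 3 with an shRNA against LYCAT (LCLAT1) after 48 hours. The deposited counts summed to 4075367 to 4930079 per control library and 3118946 to 4730453 per LYCAT shRNA library, and 11097 genes were tested. Pairs of libraries within a group differed by 1.36 to 2.49 in chi-square per degree of freedom, and pairs between the groups by 4.93 to 6.72. The first principal component held 50.1% of the variance and separated the 2 groups, and the second held 15.6%.

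LCLAT1, which encodes an acyltransferase that remodels the acyl chains of cardiolipin and phosphatidylinositol, was measured first, since it is the target of the shRNA. Its level was 56.8, 61.2 and 65.3 CPM in the control libraries and 18.9, 22.6 and 23.6 CPM in the LYCAT shRNA libraries. The mean fell from 61.1 ± 4.23 to 21.7 ± 2.45 CPM (SD, n = 3 each), or 35.5% of the control. The log2 fold change was -1.50 (SE 0.114, edgeR quasi-likelihood adjusted p = 1.15e-18). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. The knockdown was partial, since LCLAT1 counts of 89, 70 and 101 remained in the 3 LYCAT shRNA libraries.

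The question of the comparison was how the expression profile differs between cells with LYCAT shRNA, in which LCLAT1 was reduced, and cells with control shRNA. Other effects of the shRNA, or differences between the cells of the groups, cannot be told apart here from effects of the loss of LCLAT1. With LYCAT shRNA, targets of p53 and NF-kB and inflammatory genes rose on balance. Genes of the integrated stress response and unfolded protein response, tested together as a list, fell on balance, though some unfolded protein response genes did not pass. These 3 lists also passed with an estimated correlation, and 6 others, NRF2 targets and interferon-stimulated genes among them, passed with the preset correlation and not with an estimated one (adjusted p = 0.17 and 0.085 for these). Of the 11097 tested genes, 1089 rose and 1028 fell, and 118 rose and 99 fell by 2-fold or more; scaled by library totals only, 966 rose and 1127 fell. Most changes were small: 1541 of the 2117 changed genes moved by less than 1.5-fold, and the median size was 0.39 on the log2 scale. The groups did not overlap for 1967 of the changed genes (92.9%) and for 32.8% of all tested genes, where chance gives 10%. With DESeq2 1070 genes passed, against a 1.5-fold change (glmTreat) 148 passed, and without control libraries 1 and 2, described with the collagen genes, 1129 passed.

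The genes that rose most were of several kinds. WNT7B, a Wnt ligand, rose 8.68-fold from 1.23 ± 0.345 to 10.9 ± 2.59 CPM (SD, n = 3 each). Its counts were 5, 8 and 4 in the control libraries, so the size of the fold is imprecise. NT5E, a surface enzyme that makes adenosine from AMP, rose 6.14-fold from 51.0 ± 3.56 to 313 ± 8.12 CPM (log2 2.62, SE 0.0691, edgeR adjusted p = 1.02e-46). The cytokine IL11 rose 5.26-fold, from 13.5 ± 3.36 to 71.2 ± 6.89 CPM. PLTP, a phospholipid transfer protein, rose 4.86-fold from 3.13 ± 1.37 to 15.7 ± 1.54 CPM. EDA2R, a receptor of the tumour necrosis factor receptor family, rose 5.50-fold and FHOD3, a formin that acts on actin, 6.93-fold. Both rose from under 2 CPM in controls, so the sizes of these folds are imprecise. XIST, the RNA that coats the inactive X chromosome, rose 6.92-fold from 45.5 ± 2.18 to 315 ± 36.0 CPM, and the X-linked gene HDHD1 rose 4.40-fold from 5.06 ± 1.07 to 22.6 ± 1.10 CPM. SNAR-H was counted 7.31-fold higher and SNAR-F 3.12-fold lower; these small noncoding RNAs have near-identical copies among which reads can be split, so both values are uncertain.

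Among the genes that fell most, IFI27, an interferon-induced gene, fell 17.5-fold from 19.4 ± 0.606 to 1.16 ± 0.674 CPM (log2 -4.13, SE 0.291, edgeR adjusted p = 2.11e-20). Its counts were 4, 6 and 3 in the LYCAT shRNA libraries, so the size of the fold is imprecise. CHAC1, which degrades glutathione, fell 5.60-fold from 19.2 ± 2.02 to 3.57 ± 1.39 CPM. AQP3, a water and glycerol channel, fell 4.92-fold from 48.8 ± 7.88 to 9.90 ± 1.35 CPM. CPLX2, a complexin that acts in vesicle exocytosis, fell 4.31-fold from 135 ± 11.7 to 31.2 ± 3.24 CPM. CTH, which makes cysteine from cystathionine, fell 3.07-fold from 14.2 ± 0.600 to 4.61 ± 0.243 CPM. The adhesion receptor LPHN1 fell 3.1-fold, the transcription factor JDP2 2.98-fold, the sorting receptor SORL1 3.05-fold, the kinesin KIF26A 3.55-fold and the secreted protein WFDC2 2.92-fold. By size of fall LCLAT1 was number 17 among genes that met the same conditions.

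**Figure D1:**
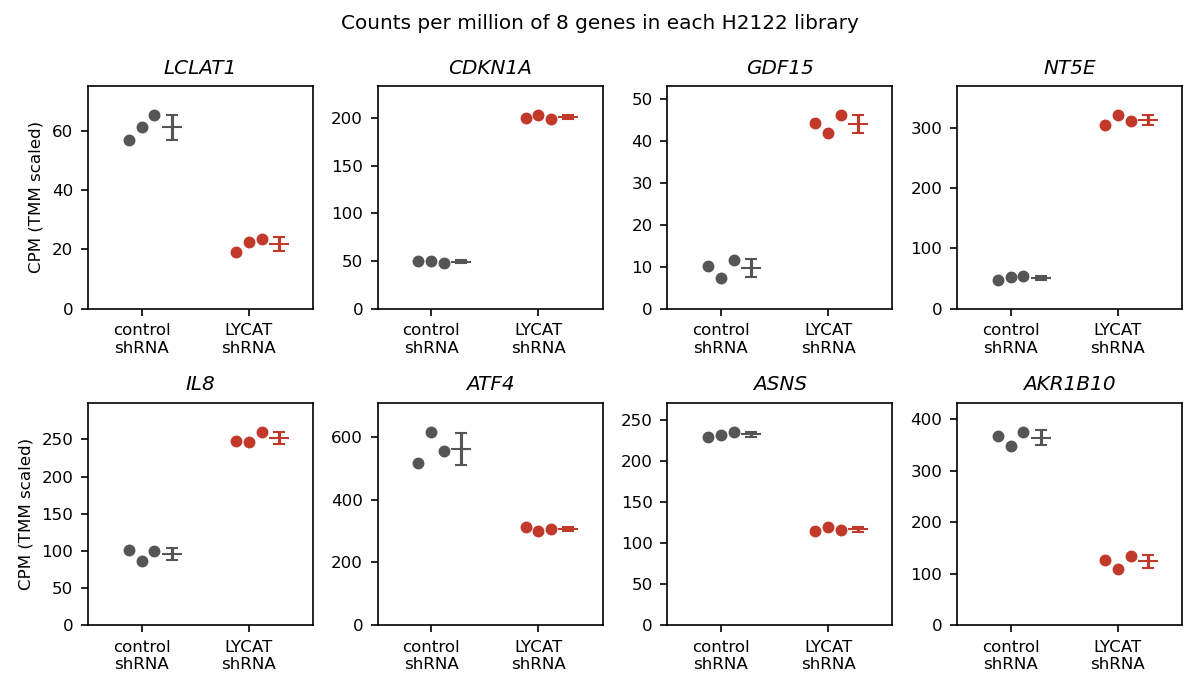
Levels in CPM (vertical axis, from 0, TMM scaled) of 8 genes in the control shRNA (grey) and LYCAT shRNA (red) libraries; points are libraries and the bar beside them is the mean with the SD of 3 libraries. The LCLAT1 libraries lie between 56.8 and 65.3 CPM with control shRNA and between 18.9 and 23.6 CPM with LYCAT shRNA, and the groups do not overlap for any of the 8 genes drawn.

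Targets of p53, a transcription factor activated by DNA damage and other stress, rose together. Of 23 tested members 18 rose and 5 did not pass, with a list median of 1.01 on the log2 scale (2.01-fold); 19 rose when adjusted over the list alone. CDKN1A, which encodes the cell cycle inhibitor p21, rose 4.07-fold from 49.3 ± 1.36 to 201 ± 2.15 CPM (log2 2.03, SE 0.0733, edgeR adjusted p = 8.08e-38). GDF15, a stress-induced cytokine, rose 4.63-fold from 9.65 ± 2.2 to 44.1 ± 2.16 CPM, and the exonuclease gene AEN rose 2.28-fold from 44.6 ± 3.78 to 102 ± 6.38 CPM. The death receptor gene FAS, named after its value was seen, had a log2 fold change of 0.06 (edgeR adjusted p = 0.867). The list passed with camera (adjusted p = 1.25e-15; adjusted p = 0.018 with an estimated correlation).

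Genes of the integrated stress response and the unfolded protein response fell. Of 30 tested members 23 fell and 7 did not pass, also when adjusted over the list alone, and the list median was -0.37. ATF4, the transcription factor at the centre of the integrated stress response, fell 1.84-fold from 564 ± 51.1 to 307 ± 6.41 CPM (log2 -0.88, SE 0.0527, edgeR adjusted p = 4.01e-23). Genes that ATF4 is known to induce fell with it: ASNS, asparagine synthetase, 2.00-fold from 233 ± 3.25 to 117 ± 3.11 CPM, and PSAT1, an enzyme of serine synthesis, 1.69-fold from 334 ± 25.1 to 198 ± 11 CPM. Among genes of the unfolded protein response, chosen after their values were seen, HERPUD1 fell by 1.055, XBP1 by 0.76, DNAJC3 by 0.31, HSP90B1 by 0.25, MANF by 0.23 and HSPA5 by 0.20 on the log2 scale. DNAJC3 did not pass without control replicate 1 or 3 or LYCAT shRNA replicate 1 or 3 (edgeR adjusted p = 0.0595 to 0.193), nor MANF without control replicate 1 or 3 or LYCAT shRNA replicate 1 (0.0655 to 0.0956). Members that did not pass, named after their values were seen, were DNAJB9 (log2 -0.29), EDEM1 (-0.28), SEL1L (-0.15, edgeR adjusted p = 0.0412 without control replicate 2), SDF2L1 (-0.04), PDIA4 (-0.04), CRELD2 (0.12) and PPP1R15A (0.05), the first 6 of which belong to the unfolded protein response. The list passed with camera (adjusted p = 1.85e-12; adjusted p = 0.046 with an estimated correlation).

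NF-kB and inflammatory genes rose on balance. Of 20 tested members 10 rose, 2 fell and 8 did not pass, with a list median of 0.37; 13 rose and 2 fell when adjusted over the list alone. IL8, a neutrophil chemokine, rose 2.64-fold from 95.5 ± 8.46 to 251 ± 7.96 CPM (log2 1.40, SE 0.0654, edgeR adjusted p = 9.06e-31). The chemokine genes CXCL1 and CCL20 rose 4.55-fold and 4.78-fold, and PTGS2, which encodes a cyclooxygenase, rose 1.59-fold. CCL20 stood at 2.76 ± 2.07 CPM in the controls, with counts of 24, 7 and 7, so the size of its fold is imprecise. TNFAIP2 and NFKBIA, the latter an inhibitor of NF-kB, fell 1.38-fold and 1.11-fold. NFKBIA passed with all libraries and without control replicate 2, and not without any of the other 5 (edgeR adjusted p = 0.0621 to 0.13). The list passed with camera (adjusted p = 1.99e-06; adjusted p = 0.046 with an estimated correlation).

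NRF2 targets, genes of the antioxidant response, fell on balance, with exceptions. Of 29 tested members 17 fell, 2 rose and 10 did not pass, with a list median of -0.18; 18 fell and 3 rose when adjusted over the list alone. Without any one library other than control replicate 2, 1 member rose. AKR1B10, an aldo-keto reductase, fell 2.92-fold from 364 ± 14.5 to 124 ± 13.0 CPM (log2 -1.55, SE 0.0613, edgeR adjusted p = 9.57e-35). AKR1C2 fell 2.03-fold from 4851 ± 142 to 2384 ± 35.8 CPM and AKR1C3 1.38-fold from 707 ± 13.7 to 514 ± 8.38 CPM, while AKR1C1 rose 1.35-fold from 1837 ± 35.9 to 2479 ± 46.0 CPM. The AKR1C genes are close paralogs whose reads can be split in counting, so their single values are uncertain; AKR1C1 and AKR1C2 together went from 6690 ± 177 to 4860 ± 81.5 CPM. The list passed with camera (adjusted p = 0.000102) but not with an estimated correlation (adjusted p = 0.17).

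Outputs of EGFR and RAS-MAPK signalling rose on balance, in 11 of 27 tested members, with 1 that fell and 15 that did not pass; 11 rose and 2 fell when adjusted over the list alone. FOSL1, a subunit of AP-1, rose 3.14-fold from 15.7 ± 0.187 to 49.5 ± 1.22 CPM (log2 1.65, SE 0.123, edgeR adjusted p = 3.86e-19). AREG, an EGFR ligand, rose 2.22-fold and PHLDA1 1.63-fold, while the phosphatase gene DUSP6, a feedback inhibitor of ERK, fell 1.26-fold. DUSP6 did not pass without control replicate 1, LYCAT shRNA replicate 2 or LYCAT shRNA replicate 3 (edgeR adjusted p = 0.322, 0.0789 and 0.188). The list median was 0.12, and it was 0.08 without control replicate 2, where 2 members fell, and 0.19 without control replicate 3. With camera the list passed (adjusted p = 0.000624) but not with an estimated correlation (adjusted p = 0.1).

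Interferon-stimulated genes fell in 5 of 22 tested members, and 17 did not pass; the count was the same adjusted over the list alone. IFI44 fell 6.99-fold from 8.32 ± 0.721 to 1.20 ± 0.360 CPM and IFI44L 2.01-fold from 30.5 ± 1.33 to 15.1 ± 0.455 CPM, besides IFI27. The counts of IFI44 were 5, 5 and 4 in the LYCAT shRNA libraries, so the size of its fold is imprecise. The other members that fell, named after their values were seen, were IFI6 (log2 -1.17) and OAS1 (log2 -0.98), the latter not without control replicate 3 or LYCAT shRNA replicate 1 (edgeR adjusted p = 0.0787 and 0.161). The list median was -0.21, and -0.13 without LYCAT shRNA replicate 3. Camera called the list (adjusted p = 0.00133) but not with an estimated correlation (adjusted p = 0.085).

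Genes of epithelial junctions and keratins fell in 11 of 33 tested members, and 22 did not pass; 14 fell when adjusted over the list alone. The keratin genes KRT7 and KRT8 fell 1.23-fold and 1.35-fold, and F11R, a tight junction adhesion molecule, fell 1.26-fold from 199 ± 13.8 to 158 ± 3.54 CPM. CDH1, which encodes E-cadherin and was named after its value was seen, fell by 0.26 on the log2 scale (edgeR adjusted p = 0.0345); it passed without control replicate 2 and not without any of the other 5 libraries (0.0559 to 0.237). The list median was -0.16, and the list passed with camera (adjusted p = 0.000831) but not with an estimated correlation (adjusted p = 0.085).

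Among mesenchymal and cell migration genes 5 of 28 tested members rose, 1 fell and 22 did not pass; 6 rose and 1 fell when adjusted over the list alone. CDH2, which encodes N-cadherin, rose 2.24-fold from 16.0 ± 0.691 to 35.6 ± 3.17 CPM, CD44, a hyaluronan receptor, 1.72-fold and the integrin gene ITGA2 1.36-fold. TGFBI, a matrix protein, fell 1.91-fold from 899 ± 33.6 to 471 ± 3.41 CPM (log2 -0.93, SE 0.0461, edgeR adjusted p = 3.32e-29). SNAI2 and LAMB3, named after their values were seen, rose by log2 1.10 and 0.29; SNAI2 did not pass without control replicate 1 or 3 or LYCAT shRNA replicate 1 or 3 (edgeR adjusted p = 0.0621 to 0.12). The list did not pass (camera adjusted p = 0.469), and its median of 0.11 and mean of -0.18 differ in sign. Without control replicate 3 the list had 4 members higher and 5 lower and a median of 0.044, and without control replicate 2 its median was 0.054.

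Collagen and matrix genes, from that list and, for COL1A2, from the markers of other cell types, differed between libraries of the same group. FN1, fibronectin, named after its values were seen, stood at 93.5, 162 and 19.6 CPM of the library total in control libraries 1 to 3 and at 31.5, 8.66 and 20.1 CPM in the LYCAT shRNA libraries. The edgeR adjusted p for FN1 was 0.238, and it passed as lower with limma-voom (0.00695) and with robust=FALSE (3.89e-06). COL1A1 passed as lower with DESeq2 (adjusted p = 0.044), limma-voom (0.000168) and robust=FALSE (8.37e-07), and COL1A2 with robust=FALSE (0.0028). COL1A1 stood at 59.9, 82.8 and 28.2 CPM and at 25.8, 16.4 and 22.7 CPM, and COL1A2 at 14.5, 23.9 and 0.982 CPM and at 5.5, 1.6 and 4.4 CPM. Of the markers of fibroblasts, endothelium and blood, 5 of 25 were abundant enough to test, and 0 of these passed with edgeR, 1 was lower at an unadjusted p under 0.05, and 1 was lower with DESeq2 and 2 with limma-voom. Without control replicate 3, 3 of the 5 passed as lower, among them COL1A1 and COL1A2 (log2 -1.67 and -2.21, edgeR adjusted p = 5.84e-11 and 6.28e-08). The median of the 5 was -1.37, and 0.489 without control libraries 1 and 2. For the mesenchymal list limma-voom called 5 members higher and 6 lower. Without control libraries 1 and 2 the mesenchymal list passed as higher (camera adjusted p = 0.033, median 0.27, 4 members higher and 1 lower). In that fit the lone control library is assumed to vary like the others.

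**Figure D2:**
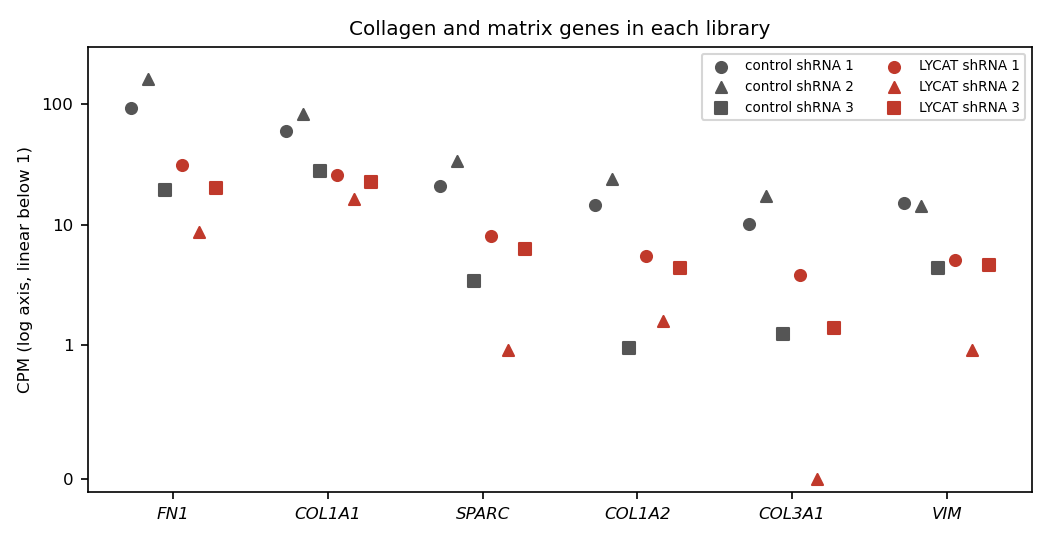
Levels in CPM of the library total (vertical axis, log scale above 1 and linear below) of 6 genes. These are the collagen and matrix genes FN1, COL1A1, SPARC, COL1A2 and COL3A1, and VIM. Each library has 1 point, control shRNA in grey and LYCAT shRNA in red. Control libraries 1 and 2 have the highest values for each of the 6 genes, such as 93.5 and 162 CPM for FN1, while control library 3 at 19.6 CPM lies among the LYCAT shRNA libraries.

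Genes of G2 phase and mitosis fell on balance by small amounts. Of 39 tested members 13 fell, 2 rose and 24 did not pass, with a list median of -0.09; 14 fell and 2 rose when adjusted over the list alone. CENPE, a centromere kinesin, fell 1.77-fold from 135 ± 20.2 to 75.9 ± 10.9 CPM and the kinetochore gene NUF2 1.3-fold from 161 ± 5.35 to 125 ± 5.68 CPM. The list median was -0.15 without control replicate 2. The phosphatase gene CDC25B fell 1.53-fold, and it lies in a run of neighbouring genes on chromosome 20 that had a median of -0.22. CCNB1, cyclin B, and PTTG1, securin, rose 1.13-fold and 1.10-fold; without control replicate 1 neither passed (edgeR adjusted p = 0.0693 and 0.226), nor PTTG1 without LYCAT shRNA replicate 1 or 2 (0.0797 and 0.309). The list passed with camera (adjusted p = 0.00418) but not with an estimated correlation (adjusted p = 0.22). Of 39 genes of S phase and replication 7 rose and 32 did not pass, among them CCNE1, cyclin E, which rose 1.69-fold from 9.99 ± 0.756 to 16.8 ± 1.79 CPM; 9 rose and 1 fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.386; median -0.002, and -0.02 to 0.0312 with 1 library left out, mean 0.04). Without any one of the LYCAT shRNA libraries 4 S phase genes rose and 0 fell, and without control replicate 1, 5 rose and 1 fell.

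Lipid genes near the function of LCLAT1 changed in both directions, where 19.1% of all tested genes changed. Of 22 tested genes of phospholipid acyl chain remodelling, AGPAT5 rose 1.3-fold from 83.2 ± 4.10 to 108 ± 4.91 CPM and LPCAT1 1.49-fold from 17.1 ± 2.40 to 25.6 ± 0.743 CPM, and 20 did not pass; both encode lysophospholipid acyltransferases. Of 18 genes of cardiolipin synthesis and transport 2 rose and 4 fell; 1 rose and 2 fell without control replicate 1 or LYCAT shRNA replicate 1, 2 rose and 2 fell without control replicate 3, and 1 rose and 3 fell without LYCAT shRNA replicate 3. TRIAP1, which acts in phosphatidic acid transfer within mitochondria and is also a p53 target, rose 1.46-fold, and STOML2 rose 1.12-fold. CRLS1, cardiolipin synthase, fell 1.18-fold from 119 ± 8.84 to 101 ± 6.79 CPM, NME4, a mitochondrial nucleotide kinase that binds cardiolipin, fell 1.35-fold, CDS1 1.26-fold, and SLMO2, named after its value was seen, fell by 0.17 on the log2 scale. CRLS1 did not pass without control replicate 1 or 3 or LYCAT shRNA replicate 1 or 3 (edgeR adjusted p = 0.0809 to 0.113), nor STOML2 without control replicate 1 or LYCAT shRNA replicate 1 or 3 (0.0889 to 0.196), nor SLMO2 without control replicate 1 or 3 or LYCAT shRNA replicate 1 or 2 (0.0565 to 0.123). Adjusted over the list alone the counts of both lists were the same, and neither list passed (camera adjusted p = 0.507 and 0.745).

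Of 16 tested genes of mitochondrial fission and fusion 4 rose and 12 did not pass, where 19.1% of all tested genes changed: the fission factor genes MFF and SMCR7L rose 1.23-fold and 1.22-fold, the fusion gene MFN2 1.22-fold, and GDAP1, named after its value was seen, by log2 0.58, not passing without control replicate 2 or 3 or LYCAT shRNA replicate 1 (edgeR adjusted p = 0.0796 to 0.477). The count was the same adjusted over the list alone. Of 41 nuclear genes of oxidative phosphorylation 6 rose and 1 fell, among them UQCRFS1 at 1.16-fold higher and SDHC at 1.13-fold lower, which did not pass without control replicate 1 or 3 or LYCAT shRNA replicate 1 or 2 (edgeR adjusted p = 0.156 to 0.224); 4 rose and 1 fell when adjusted over the list alone. These counts depended on the libraries: 4 rose without control replicate 1 or LYCAT shRNA replicate 2, 3 without control replicate 3 and 2 without LYCAT shRNA replicate 1, with 0 that fell in each, while 8 rose and 4 fell without control replicate 2 and 2 rose and 1 fell without LYCAT shRNA replicate 3. The 2 lists did not pass (camera adjusted p = 0.372 for each).

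Genes of fatty acid oxidation fell on balance, 7 of 18 tested members falling, 2 rising and 9 not passing, with a list median of -0.19; 8 fell and 2 rose when adjusted over the list alone. Without control replicate 3, 0 rose and 5 fell, without LYCAT shRNA replicate 3, 1 rose and 4 fell, and without any one of the other libraries 1 rose and 5 or 6 fell. CPT1A, which commits fatty acids to mitochondrial import, fell 1.27-fold from 217 ± 11.5 to 170 ± 5.87 CPM and ECH1 1.40-fold. CPT2 rose 1.31-fold and did not pass without control replicate 2 or 3 or LYCAT shRNA replicate 1 (edgeR adjusted p = 0.0655 to 0.191). The list passed with camera at adjusted p = 0.0348 but not with an estimated correlation (adjusted p = 0.17). It also did not pass without control replicate 3, LYCAT shRNA replicate 1 or LYCAT shRNA replicate 3 (camera adjusted p = 0.081, 0.065 and 0.066). Of 17 genes of fatty acid synthesis and desaturation 5 rose and 2 fell, with ELOVL5, a fatty acid elongase, 1.42-fold higher and SREBF1, a lipogenic transcription factor, 1.34-fold lower (edgeR adjusted p = 0.056 without LYCAT shRNA replicate 1); 6 rose and 2 fell when adjusted over the list alone. Of these genes 3 rose and 1 fell without control replicate 1, 4 and 1 without control replicate 3, 4 and 0 without LYCAT shRNA replicate 1, and 3 and 2 without LYCAT shRNA replicate 2. That list did not pass with camera (adjusted p = 0.111) and passed with fry, which does not compare it with other genes (adjusted p = 0.00885). Of 24 genes of cholesterol synthesis and uptake 0 passed with edgeR, DESeq2 or limma-voom, and 4 were higher at an unadjusted p under 0.05 (list median 0.0154, mean -0.007). FDPS stood at 234 ± 19.8 and 230 ± 4.77 CPM and CYP51A1 at 260 ± 21.7 and 242 ± 17.6 CPM, which passed as lower without control replicate 2 (edgeR adjusted p = 0.0211), where 1 member of the list rose and 2 fell. The cholesterol list median was 0.0606 without LYCAT shRNA replicate 1, -0.0406 without LYCAT shRNA replicate 3, -0.00122 without control replicate 1, 0.00529 without control replicate 2, and 0.0234 and 0.0235 without control replicate 3 and LYCAT shRNA replicate 2.

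The other lists did not pass with camera on all libraries. Of 35 genes of hypoxia and glycolysis 6 rose and 2 fell, with PFKP 1.20-fold higher and VEGFA 1.25-fold lower (edgeR adjusted p = 0.173 without control replicate 1 and 0.0536 without LYCAT shRNA replicate 1 for VEGFA; camera adjusted p = 0.474; median 0.05, mean -0.01). Of the hypoxia genes 6 rose and 0 fell without control replicate 1, 6 and 4 without control replicate 2, 5 and 4 without control replicate 3, 5 and 0 without LYCAT shRNA replicate 1, 3 and 1 without LYCAT shRNA replicate 2, and 1 and 1 without LYCAT shRNA replicate 3; the median was 0.0243 without control replicate 3 and 0.0261 without LYCAT shRNA replicate 2. Of 26 apoptosis regulators 4 rose and 1 fell: BBC3, a proapoptotic p53 target, rose 1.77-fold from 37.8 ± 1.96 to 67.6 ± 6.39 CPM, MCL1 rose 1.24-fold, CYCS rose 1.16-fold, BIRC3, named after its value was seen, rose by log2 0.40, and PMAIP1 fell 1.31-fold (edgeR adjusted p = 0.142 without LYCAT shRNA replicate 1). The apoptosis list had a camera adjusted p of 0.0594; it passed without control replicate 3 (0.028), without LYCAT shRNA replicate 3 (0.041) and with fry (0.049), and without control replicate 2 it had 4 members higher and 3 lower. Of 29 lysosome and autophagy genes ULK1, a kinase that starts autophagy, fell 1.58-fold and the protease gene CTSD 1.3-fold (camera adjusted p = 0.86); 1 rose and 3 fell without control replicate 1, and 1 rose and 2 fell without control replicate 2 or LYCAT shRNA replicate 3. Of 38 ribosomal protein genes, a sign of RNA quality, 9 rose, the X-linked RPS4X by 1.3-fold and RPL3 by 1.16-fold. The ribosomal list had a camera adjusted p of 0.0594; it passed as higher without control replicate 2 (0.02), without LYCAT shRNA replicate 2 (0.042) and with camera on ranks (0.029). Without control replicate 2, 14 ribosomal genes rose and 2 fell, and without LYCAT shRNA replicate 1 or 3, 3 rose. Of 7 histone genes HIST1H4C fell 1.21-fold (edgeR adjusted p = 0.106 without control replicate 1; camera adjusted p = 0.474 for the list). Of 25 lung lineage markers 5 could be tested (camera adjusted p = 0.942; median -0.34, and -0.173 without LYCAT shRNA replicate 1, mean 0.07). Adjusted over each list alone, 7 hypoxia genes rose and 4 fell, 11 ribosomal genes rose, and the counts of apoptosis, lysosome and histone genes were the same.

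**Figure D3:**
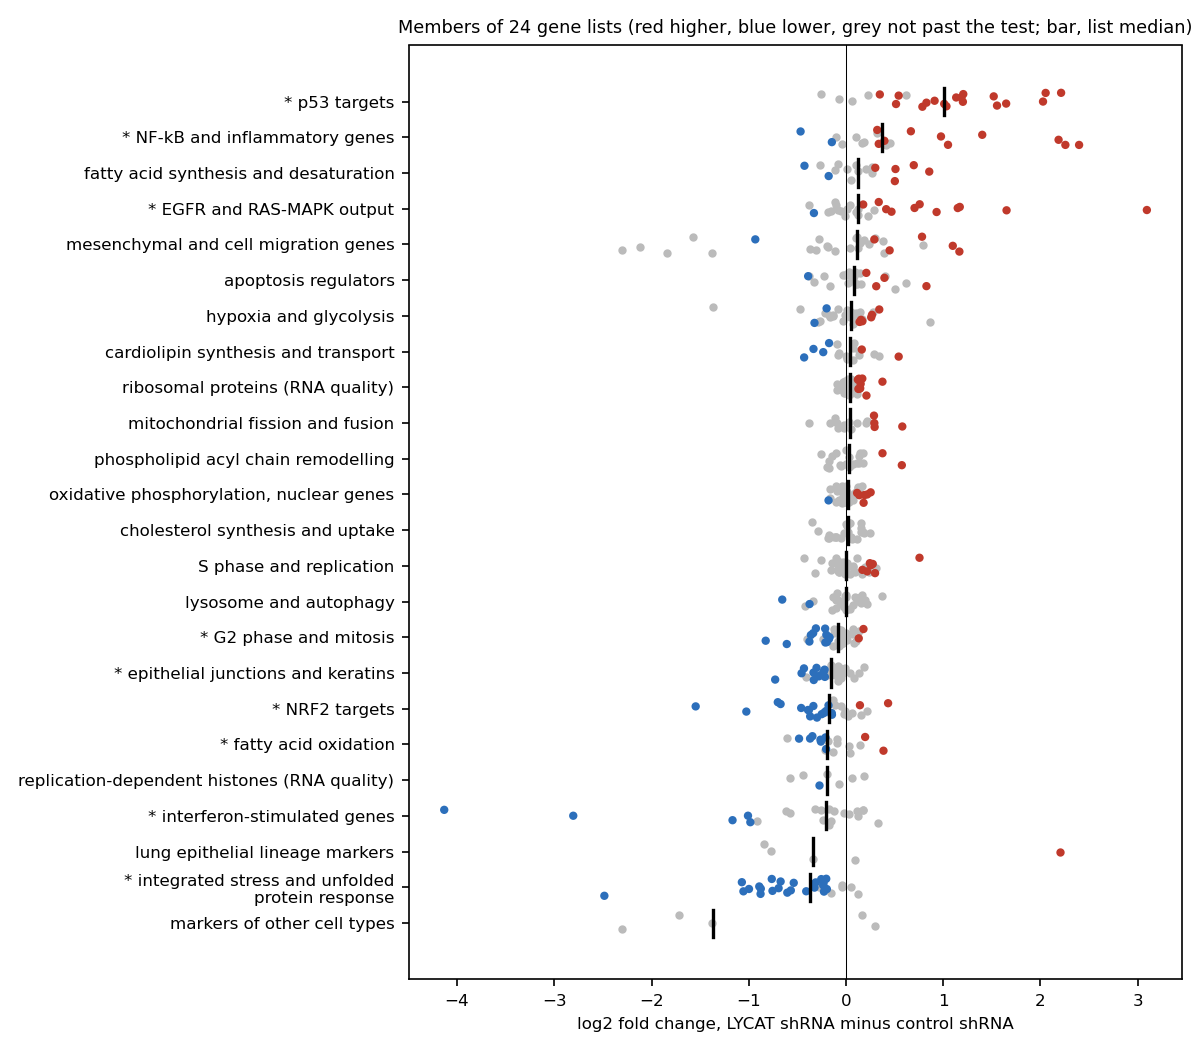
Log2 fold changes (horizontal axis, LYCAT shRNA minus control shRNA) of the tested members of 24 gene lists, with 1 point per gene, red for higher, blue for lower and grey for not past the edgeR test; the black bar is the list median and an asterisk marks the 9 lists that passed camera with the preset correlation. The p53 targets have the highest median, at 1.01, and the markers of other cell types the lowest, at -1.37 over 5 genes that did not pass, a median that was 0.489 without control libraries 1 and 2.

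Of the 24 lists 9 passed with the preset correlation, 3 as higher and 6 as lower. With a correlation estimated from the data the lists of p53 targets, stress response genes and NF-kB genes passed.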

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

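The fits with GC and length corrected offsets, with thinned counts and without both control shRNA libraries 1 and 2 were chosen after seeing the data. DESeq2 called 1070 genes, 582 higher and 488 lower, of which 1053 were shared with the 2117 called by edgeR; its filtering gave 4079 genes no adjusted p, and the cause of the lower count was not tested. The test against a 1.5-fold change called 148 genes, 84 higher and 64 lower, as its construction makes it stricter. Without both control shRNA libraries 1 and 2 there were 1129 genes, 573 higher and 556 lower, of which 1019 were shared; this fit has fewer samples, and the lone control library is assumed to vary like the others. With the correlation between genes estimated from the data 3 lists passed, where 9 passed with the preset value.

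Under the other alternatives that kept all 6 libraries, the number of genes called lay between 1725 (counts thinned to the shallowest library) and 2128 (no filter on low counts). Scaled by library totals only 966 rose and 1127 fell, and with GC and length corrected offsets 1199 rose and 917 fell, so which direction held more genes depended on the scaling. Leaving out each library in turn gave 1448 to 2228 genes, 742 to 1128 higher and 700 to 1100 lower, and 8 to 10 lists. The LCLAT1 log2 fold change lay between -1.40 and -1.61 and passed under each alternative run. Of 1372 values of the other named genes under alternatives other than the 1.5-fold test and leaving out 1 library, 1283 kept their side of the threshold, 83 lost the call and 6 gained it. Against a 1.5-fold change 73 of 125 lost the call, and with a library left out 83 of 750 lost it and 4 gained it. No called value changed direction. Of 213 list values under alternatives other than leaving out 1 library, 201 kept their side of the threshold, 8 lost the call and 4 gained it. With a library left out 3 of 144 lost the call, each for fatty acid oxidation, and 4 gained it, for the apoptosis and ribosomal lists. Only 9 of 24 lists were called in the main fit, so most of these values had no call to lose.

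The replicate numbers are shared by the groups, but libraries of the same number did not deviate together (correlations of 0.0051, -0.064 and -0.048 across genes). No library correlated best with its own number. With a replicate block 2046 genes were called, 1044 higher and 1002 lower, and 8 lists, fatty acid oxidation not among them (camera adjusted p = 0.059).

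The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone, 1 of 10, reached its 2117 genes, 1089 higher, 1028 lower and 9 lists. The highest of the others gave 0 genes in either direction and 5 lists. Each other split mixes libraries of both shRNAs, which puts the group difference into the spread within its groups. Few genes were therefore likely to be called there in any case, and these counts cannot decide whether the difference arose by chance. Depth limits the genes of low abundance, such as IFI27 with 3 to 6 counts per LYCAT shRNA library.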

Other observations

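The 8 pathway lists, the symbol families, and the tests on X-linked genes were chosen after the results were seen. The tests on chromosome 20 and the rank correlation with a second list of fibroblast genes were written down before their values were computed. The patterns that these tests address had already been seen in the same data. Pearson's r for the second fibroblast list was not written down beforehand.

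Genes that charge and import amino acids fell in part. Of 20 cytosolic aminoacyl-tRNA synthetase genes 9 fell and 2 rose. AARS, the alanine enzyme, fell from 86.8 ± 4.75 to 54 ± 2.42 CPM (SD, n = 3 each; 0.622-fold), CARS from 102 ± 0.691 to 65 ± 2.48 CPM, GARS from 291 ± 20.8 to 196 ± 7.5 CPM and MARS from 217 ± 20.4 to 141 ± 6.71 CPM. NARS and RARS rose 1.19-fold and 1.16-fold. Of 15 tested amino acid transporter genes 8 fell and 2 rose: SLC7A5, a transporter of large neutral amino acids, fell from 81.5 ± 11.6 to 53.1 ± 2.72 CPM, and SLC6A9, a glycine transporter, from 6.99 ± 2.19 to 2.03 ± 0.687 CPM. Neither list passed as a set (camera adjusted p = 0.0842 for each over 8 lists; adjusted p = 0.3 and 0.29 with an estimated correlation).

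The other 6 lists did not pass either. Of 17 tested YAP and TAZ targets 5 rose, among them F3, tissue factor, at 2.47-fold (camera adjusted p = 0.332; median -0.11, mean 0.20), and 5 of the 22 genes listed are also in lists fixed before. Of 15 heat shock chaperone genes 6 rose, HSPB1 by 1.27-fold (camera adjusted p = 0.16). Of 18 sphingolipid genes 4 rose and 1 fell, with SGMS2, a sphingomyelin synthase, at 1.5-fold and SPHK1, a sphingosine kinase, at 1.29-fold (camera adjusted p = 0.115). Of 29 genes of translocation into and export from the endoplasmic reticulum 6 rose and 1 fell (camera adjusted p = 0.138). Of 11 Wnt targets 3 rose and 2 fell (camera adjusted p = 0.515), and of 11 genes of phosphatidylcholine and phosphatidylethanolamine synthesis PTDSS1 rose 1.11-fold (camera adjusted p = 0.635; median 0.08, mean -0.002). Of 71 families of genes that share a symbol stem, the genes with the stem CD passed, with 7 of 26 higher (camera adjusted p = 0.0202, and 0.775 with an estimated correlation).

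Genes at one end of chromosome 20 were lower as a run. In the window of 40 tested genes from C20orf96 to SLC23A2 the median log2 fold change was -0.22 (0.861-fold), 33 of the 40 lay below 0, 16 were called lower and 1 higher. Shuffling the order of genes gave a window median as far from 0 in a share of 0.02 of 1000 shuffles. This argues against random placement of the changed genes. After correction for GC content and length the median was -0.235, no nearer to 0 than before, which argues against a GC or length trend. The shuffled limit of 0.202 came from uncorrected values, and the corrected values were not shuffled. A smaller dose of that chromosome end in the LYCAT shRNA cells and regulation of these genes after loss of LCLAT1 both stay open, and neither was tested.

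XIST and some X-linked genes were higher with LYCAT shRNA. The 334 other X-linked genes differed from autosomal genes by 0.000152 in median log2 fold change (95% bootstrap interval -0.038 to 0.0275), which argues against a higher dose of a whole active X chromosome. Of 22 tested genes known to escape X inactivation, XIST, HDHD1 and RPS4X left out, 7 rose, among them PRKX (log2 0.71), SYAP1 (0.65) and EIF1AX (0.46), and their median of 0.18 lay above the -0.01 of the other X-linked genes (one-sided permutation p = 0.00088). Several of these had been seen to be higher before the list was tested. Abundant listed genes that did not pass included DDX3X (log2 0.06), SMC1A (0.05), UBA1 (0.009), KDM5C (-0.06) and USP9X (-0.07). A higher share of cells with an inactive X chromosome in the LYCAT shRNA libraries may account for the higher median of the listed genes. Not all of these genes rose, and the rises of XIST and HDHD1 were not part of that test. Whether such a share would reflect different cells in the 2 arms or the knockdown stays open.

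The levels of FN1, COL1A1, COL1A2, COL3A1, SPARC and VIM were unequal between libraries. Their sum was 214, 334 and 57.9 CPM in control libraries 1 to 3 and 79.7, 28.5 and 59.5 CPM in the LYCAT shRNA libraries, and the highest control library was 5.76 times the lowest. An effect of the shRNA on these genes was not tested apart from this spread. A second list of 23 fibroblast genes, 6 of them also in lists fixed before and 2 above 5 CPM in each library, summed to 115, 137 and 86.1 CPM and to 66, 49.4 and 68.3 CPM. Over the 6 libraries the sums had Spearman's rho of 0.771 (exact one-sided permutation p = 0.0514) and Pearson's r of 0.947 (exact one-sided permutation p = 0.00833), and r was 0.526 without the 2 libraries farthest from the median, so the relation rests on those. RNA of a fibroblast-like cell type in control libraries 1 and 2 could account for the levels. The rank correlation missed its threshold of 0.05, and this stays open. Both correlations took the groups together, so an effect of the shRNA on both lists could also produce them. The second sum was higher in each control library, control library 3 at 86.1 CPM included, than in any LYCAT shRNA library.

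Control library 1 also had the highest levels of a set of genes chosen after their values were seen. These were LIN28A (15.8 CPM of the library total, other libraries 0.962 to 4.87), POU5F1B (22.7, others 0.641 to 4.26), POU5F1 (15.8, others 0.641 to 3.45), TUBB2B (32, others 0.962 to 8.32), TDGF1 (10.8, others 0 to 1.42), L1TD1 (5.41, others 0 to 1.9), DPPA4 (5.19, others 0 to 1.83) and the interferon-induced IFITM1 (34, others 4.17 to 12.2). POU5F1 and POU5F1B are near-identical copies, so their single values are uncertain. Whether reads or RNA of another sample are in that library was not tested; without control replicate 1 there were 1607 genes called.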
